A study of Homo sapiens with 5 samples.

How the data were processed

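Jurkat T cells, a human T-cell leukemia line, were sequenced without treatment (Control, 2 libraries) or after 15 h with 50 µM vitamin K1 (VK1, 3 libraries). Per the labels' protocols, mRNA was isolated from total RNA, fragmented and copied to cDNA, and libraries were sequenced on an Illumina NovaSeq instrument in paired-end mode with reads of 150 bases. HISAT2, StringTie and SAMtools and the hg38 build are named in the submitters' processing notes without versions. The counting method and the use of strand are not given in the sources used here, so genes that overlap, antisense pairs and near-identical copies are uncertain. EEF1A1P5, a pseudogene, held 6153 to 6924 CPM against 1405 to 1753 CPM for EEF1A1.

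The deposited table holds raw counts per gene, as whole numbers with different totals per library, and the gene positions used here were taken from it. The 2 Control columns carry the names of their samples. The 3 VK1 columns name the group and a number (6001, 6002, 6003) that is in no label, so they were used as replicates of the group, called VK1 A, B and C, with no replicate number. The deposited tables also had 4 columns of per-sample values, from 1 library, that matched no sample, and these were not used. FPKM columns were not used. A deposited annotation table with KEGG pathway names per gene was used for exploratory terms.

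Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (minimum count 10, minimum total count 15), libraries were scaled by TMM, dispersions were estimated robustly and a quasi-likelihood model with the group as its term was fitted to all 5 libraries. Tests were two-sided, with Benjamini-Hochberg adjustment at 0.05. Standard errors were taken as the size of the log2 fold change over the square root of the F statistic. The biological coefficient of variation was 14.8%. CPM values are TMM-normalised unless stated. Those of EEF1A1 and EEF1A1P5, and those used to find genes with counts at 2 levels, were scaled by library size alone. On simulated counts for this comparison, with known fold changes in some of 14105 genes, 26.2% of genes changed 1.5-fold, 74.6% of those changed 2-fold and 96.9% of those changed 4-fold were recovered, with 1 false call among 128. Simulated changes of 1.5-fold were thus mostly missed at this depth and number of libraries. The simulated genes varied by the dispersion trend alone, without jumps of single libraries. The share of false calls and the recovery may therefore differ in the real counts.

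The groups, the test, 34 gene lists with 802 different genes (784 matched) and the rule for naming genes were chosen before the data were examined. The lists cover 27 biological themes, 2 signs of RNA quality and 5 sets of markers of other cell types. The 29 lists with at least 5 tested genes were compared with the other genes by camera (limma 3.58.1) with a preset correlation of 0.01. After adjustment over the lists 5 passed, and 1 passed with an estimated correlation. The latter test rests on the 3 residual degrees of freedom of the fit and so has less power. The rule named the 6 genes with the largest rise and the 6 with the largest fall among genes past the threshold with a mean of at least 5 CPM and no overlap between groups. It also named the 3 members with the smallest p in each biological list past the set test, the 1 such member in each other biological list, and core genes of vitamin K metabolism, among them VKORC1, VKORC1L1, GGCX, AIFM2 and NQO1. Some genes that the rule names are not reported here.

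The alternatives were DESeq2 1.42.0, limma-voom, RLE or upper-quartile scaling, no filter on low counts, a filter of 1 CPM in 2 libraries, a minimum log2 fold change of 1, an estimated correlation or fry for the lists, and leaving out each library in turn. Where a Control library was left out, the remaining one was assumed to vary like the VK1 libraries. Leaving out the 117 genes with counts at 2 levels in a pattern other than Control against VK1 was added after seeing the data; the 9 in that pattern stayed in. The median log2 fold change of all genes was 0.001 with TMM, 0.002 with RLE and -0.009 with upper-quartile scaling. Figures were drawn with matplotlib 3.10.9.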

Results

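Gene expression was measured by RNA sequencing in Jurkat T cells, a human line established from an acute T-cell leukemia. The 3 VK1 libraries came from cells kept for 15 h in medium with 50 µM VK1, that is vitamin K1 (phylloquinone), and the 2 Control libraries from cells labelled as receiving no medication. The labels do not say whether the Control cells received a solvent. Counts totalled 13904549 and 12205889 in Control 1 and Control 2, and 13712619, 14537759 and 11110128 in VK1 A, B and C. These letters follow the order of the columns and pair no library with another. The table listed 50868 genes, of which 23660 had at least 1 count and 14313 were tested. Mitochondrially encoded genes took 6.21% to 7.31% of the counts, and MT-CO1 was the most abundant gene in each library. Pearson correlations of log2 CPM (counts scaled by library size) across genes were 0.984 between the Control libraries, 0.981 to 0.984 among the VK1 libraries and 0.979 to 0.984 between groups; genes are not independent replicates. No pair of libraries matched within sampling noise, since chi-square per degree of freedom was at least 10.9. Nothing in the labels says that the libraries came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

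The comparison of VK1 with Control asked which transcripts differed in Jurkat cells after exposure to vitamin K1. Genes for making and taking up cholesterol were higher with VK1, while 3 genes driven by the liver X receptors (LXR), which sense oxysterols, were lower. MSMO1, a sterol demethylation enzyme, rose from 31.8 ± 6.67 CPM (SD, n = 2) to 117 ± 4.41 CPM (SD, n = 3), a 3.67-fold difference. ABCG1, a transporter that exports cholesterol, fell from 9.48 ± 1.36 CPM (SD, n = 2) to 0.986 ± 0.383 CPM (SD, n = 3). RAG1, a subunit of the recombinase that assembles antigen receptor genes, fell from 397 ± 3.11 CPM (SD, n = 2) to 218 ± 1.20 CPM (SD, n = 3). In total 22 genes were higher and 10 lower at an adjusted p under 0.05 by edgeR's quasi-likelihood test, and 13 and 5 of these differed by at least 1 on the log2 scale. All 32 genes had CPM ranges that did not overlap between the groups, as did 26.5% of the tested genes, against the 20% that chance gives for 2 libraries against 3. Of the 32 genes, 17 belonged to the lists for cholesterol synthesis and uptake, fatty acid synthesis or LXR targets, which together held 45 tested genes.

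Of the 24 tested genes for cholesterol synthesis and uptake, 12 were higher over all genes tested and 22 adjusted over the list alone, none was lower, and all 24 had a positive log2 fold change. The median was 0.85, or 1.81-fold, and the list stood above the other genes by camera (adjusted p = 5.641e-31, and adjusted p = 0.0274 with an estimated correlation). MSMO1 (ENSG00000052802, chromosome 4, 165327623 to 165343160) rose by 1.88 (SE 0.14) on the log2 scale, with an edgeR adjusted p of 0.000811. IDI1 (ENSG00000067064, chromosome 10, 1039908 to 1049170), which isomerises isopentenyl diphosphate, rose 2.48-fold with a log2 fold change of 1.31 (SE 0.08). INSIG1 (ENSG00000186480, chromosome 7, 155297776 to 155310235), which retains the SREBP transcription factors in the endoplasmic reticulum, rose 2.35-fold from 108 ± 0.358 CPM (SD, n = 2) to 255 ± 14.8 CPM (SD, n = 3). Further members past the threshold included ACAT2, CYP51A1, FDFT1, FDPS, LSS, SQLE and STARD4. ACAT2 overlaps SOD2 and TCP1 in position and STARD4 overlaps STARD4-AS1, so the values of ACAT2 and STARD4 are uncertain. Among these further members SQLE, squalene epoxidase, rose 2.33-fold and LSS, lanosterol synthase, rose 1.87-fold. FDPS had the smallest rise of the 12, with a log2 fold change of 0.59 (SE 0.08). These members, like NSDHL, HMGCS1 and SREBF2, were singled out after their values were seen. NSDHL (log2 fold change 0.73, edgeR adjusted p = 0.0507), HMGCS1 (1.55, SE 0.39, adjusted p = 0.574) and SREBF2, which encodes the main activator of the pathway (0.45, adjusted p = 0.116), did not pass over all genes tested.

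Of 7 tested LXR targets, 3 were lower over all genes tested and the same 3 adjusted over the list alone, while 6 had a negative log2 fold change. The median was -0.38, and the list stood below the other genes by camera (adjusted p = 6.260e-06), but not with an estimated correlation (adjusted p = 0.199). ABCG1 (ENSG00000160179, chromosome 21, 42199689 to 42297244) fell by 3.22 (SE 0.30) on the log2 scale, with an edgeR adjusted p of 0.00333. MYLIP (ENSG00000007944, chromosome 6, 16129125 to 16148248), a ubiquitin ligase, fell from 8.65 ± 0.582 CPM (SD, n = 2) to 1.49 ± 0.165 CPM (SD, n = 3). SREBF1 (ENSG00000072310, chromosome 17, 17810399 to 17837002), an activator of lipid synthesis genes, fell by 0.84 (SE 0.09) on the log2 scale; its position overlaps that of RAI1. The list also held the genes for LXR themselves, NR1H3 (log2 fold change -0.38, edgeR adjusted p = 0.677), which lay at the list's median, and NR1H2 (0.02, adjusted p = 0.985). These members were singled out after their values were seen and did not pass.

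Among 15 tested genes of fatty acid synthesis, SCD and FADS1 were higher and SREBF1, also an LXR target, was lower. Adjusted over the list alone 3 were higher, ELOVL6 being the third, and 1 was lower. The median was 0.20 and 12 members had a positive log2 fold change; camera gave an adjusted p of 0.000746, and an adjusted p of 0.338 with an estimated correlation. SCD (ENSG00000099194, chromosome 10, 100347124 to 100364834), which desaturates stearoyl-CoA, rose 2.06-fold from 127 ± 0.593 CPM (SD, n = 2) to 263 ± 4.04 CPM (SD, n = 3). FADS1 (ENSG00000149485, chromosome 11, 61799625 to 61829318), a fatty acid desaturase whose position overlaps that of FADS2, rose 1.52-fold (edgeR adjusted p = 0.0304). The call of FADS1 was lost, at adjusted p 0.0645 to 0.142, when Control 1, Control 2, VK1 A or VK1 B was left out, and that of the list without Control 1 (camera adjusted p = 0.0603).

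**Figure D1:**
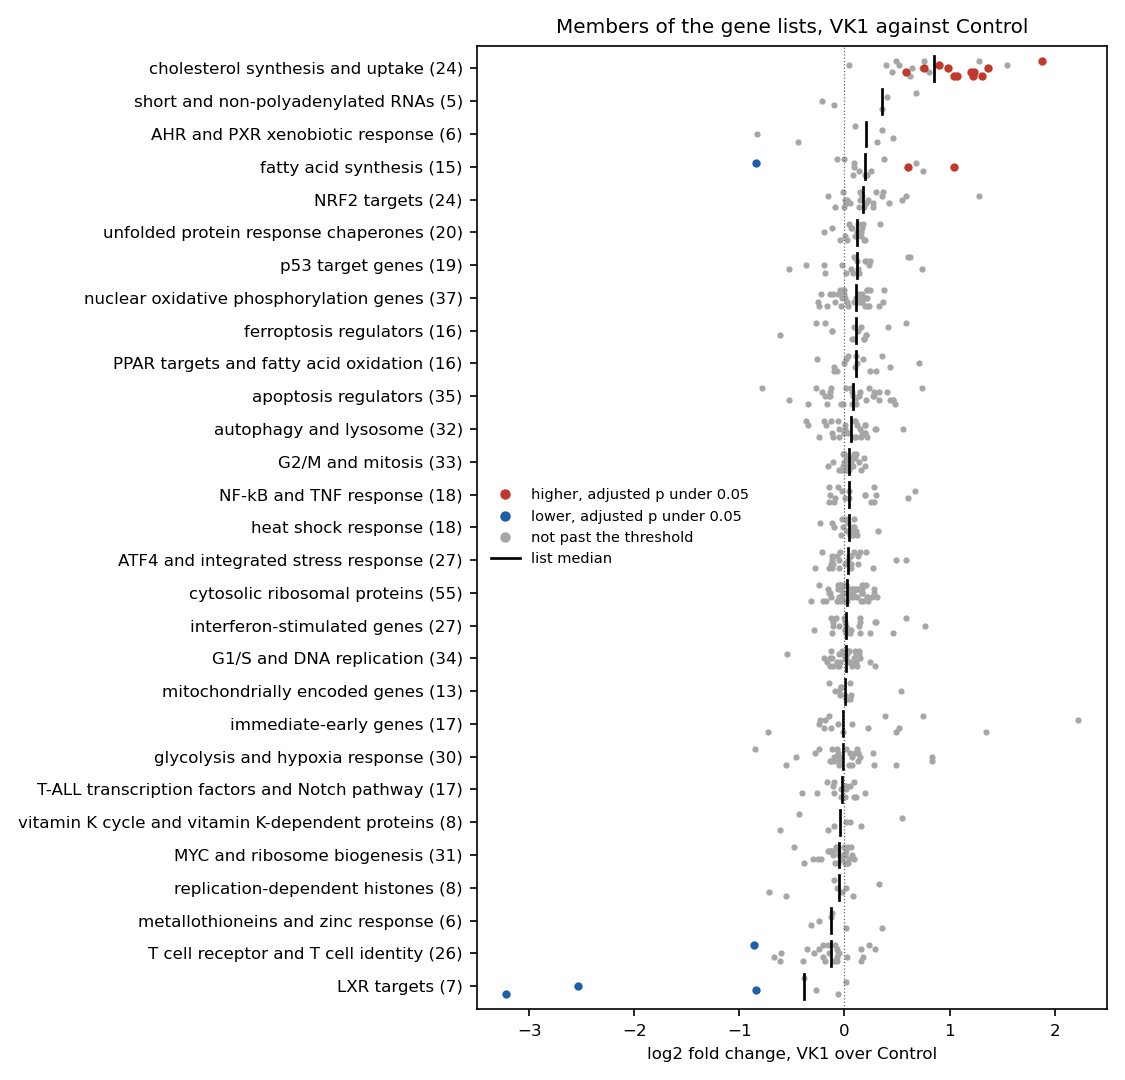
Log2 fold change of VK1 over Control (horizontal axis) for each tested member of the 29 lists with at least 5 tested genes, whose number is in brackets; points are genes, coloured where the edgeR adjusted p was under 0.05, and black lines are list medians. Cholesterol synthesis and uptake lay at a median of 0.85 and LXR targets at -0.38.

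Outside these 3 lists, 8 genes were higher and 7 were lower. UBFD1 (ENSG00000103353, chromosome 16, 23557362 to 23574389) rose 3.50-fold from 30.3 ± 5.00 CPM (SD, n = 2) to 106 ± 2.29 CPM (SD, n = 3). GLO1 (ENSG00000124767, chromosome 6, 38675925 to 38703141), glyoxalase I, which detoxifies methylglyoxal, rose 2.49-fold from 127 ± 6.34 CPM (SD, n = 2) to 315 ± 15.7 CPM (SD, n = 3). ZNF551 (ENSG00000204519, chromosome 19, 57681969 to 57717301), a zinc finger gene, fell by 2.62 (SE 0.17) on the log2 scale, from 26.5 ± 1.48 CPM (SD, n = 2) to 4.32 ± 0.746 CPM (SD, n = 3). MAP1S (ENSG00000130479, chromosome 19, 17719242 to 17734516), a microtubule-associated protein gene, fell by 1.37 (SE 0.15) and JMJD4 (ENSG00000081692, chromosome 1, 227730425 to 227735411) by 1.31 (SE 0.12). STAMBP (ENSG00000124356, chromosome 2, 73828916 to 73873659), a deubiquitinase gene, fell by 0.77 (SE 0.10; edgeR adjusted p = 0.0262), and this call was lost, at adjusted p 0.0615 to 0.102, without Control 1, Control 2, VK1 A or VK1 B. UBFD1 overlaps EARS2 and JMJD4 lies within SNAP47, so their values are uncertain. Other divisions of the 5 libraries into 2 and 3 gave 6 to 17 genes outside the lipid lists, against these 15, which include RAG1.

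**Figure D2:**
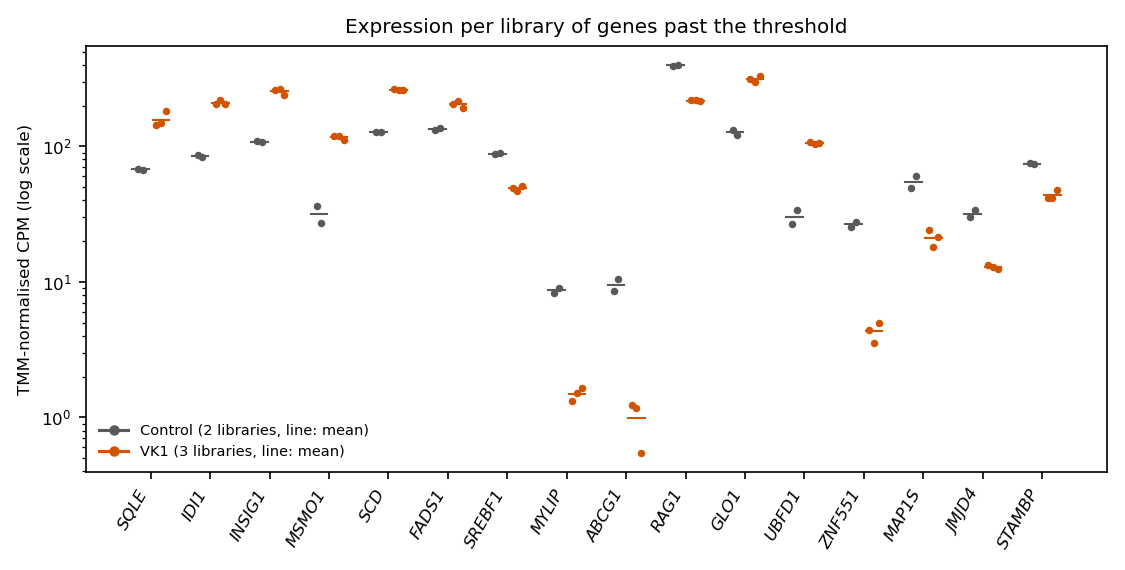
TMM-normalised CPM (log axis) of 16 genes past the threshold in the 2 Control libraries and the 3 VK1 libraries; points are libraries and lines are group means. INSIG1 lay at 108 and 109 CPM in Control and between 239 and 267 CPM with VK1, and ABCG1 between 0.546 and 1.24 CPM with VK1.

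In the list for the T cell receptor and T cell identity, 1 of 26 tested genes was lower, 2 were lower adjusted over the list alone, and 20 had a negative log2 fold change. The median was -0.13, and camera gave an adjusted p of 0.0108 (adjusted p = 0.419 with an estimated correlation). RAG1 (ENSG00000166349, chromosome 11, 36510709 to 36593156) fell by 0.86 (SE 0.07) on the log2 scale, with an edgeR adjusted p of 0.000977. RAG2 (chromosome 11, 36575574 to 36598279), its partner in the recombinase, had a log2 fold change of -0.61 (SE 0.13, adjusted p = 0.211), and TRBC1, a T cell receptor constant segment, of -0.36 (adjusted p = 0.574). The positions of RAG1 and RAG2 overlap, so the division of reads between them is uncertain. RAG2 passed by DESeq2 (adjusted p = 0.0290) and without a filter on low counts (edgeR adjusted p = 0.0330). DNTT, the polymerase that adds nucleotides at receptor gene joints, was looked at after its values were seen and had a log2 fold change of -0.78 (SE 0.12, adjusted p = 0.0519). The call of the list was lost without Control 2 (camera adjusted p = 0.160) and without VK1 C (0.0912).

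None of the 24 tested NRF2 targets, genes of the antioxidant response, passed over all genes tested, although 20 had a positive log2 fold change, with a median of 0.18. The list stood above the other genes by camera (adjusted p = 0.000491), but not with an estimated correlation (adjusted p = 0.199). SLC7A11, the cystine transporter, was the 1 member higher adjusted over the list alone, with a log2 fold change of 0.59 (SE 0.11, edgeR adjusted p = 0.163 over all genes). It passed by DESeq2 (adjusted p = 0.00800) and without a filter on low counts (edgeR adjusted p = 0.0125). OSGIN1 had a log2 fold change of 1.28 (SE 0.38, adjusted p = 0.480) and GCLM, the modifier subunit of the glutathione synthesis enzyme, 0.37 (SE 0.12, adjusted p = 0.556). Across all tested genes, 1121 had an unadjusted p under 0.05, 7.83% of those tested.

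No gene for the vitamin K cycle passed the test: 8 members of that list were tested, with a median log2 fold change of -0.04 (camera adjusted p = 0.644). VKORC1, the vitamin K epoxide reductase, was at 24.5 ± 2.53 CPM (SD, n = 2) in Control and 27.4 ± 4.82 CPM (SD, n = 3) with VK1. Its log2 fold change of 0.16 ranged from 0.06 without Control 1 to 0.30 without VK1 B. VKORC1L1, its paralog, had a log2 fold change of 0.02 (SE 0.09), and GGCX, the vitamin K-dependent carboxylase, of 0.05 (SE 0.11; 0.08 without Control 1 and 0.02 without Control 2). AIFM2 (FSP1), which reduces vitamin K, lay at -0.61 (SE 0.28), and NQO1, a quinone reductase, at 0.55 (SE 0.22; 0.28 without Control 1 and 0.87 without Control 2). Their edgeR adjusted p values were 0.611 or more. The position of GGCX overlaps that of MAT2A (629 CPM in Control and 619 CPM with VK1, scaled by library size alone). VKORC1 overlaps AC135050.2 and AIFM2 overlaps MACROH2A2, so the values of GGCX, VKORC1 and AIFM2 are uncertain.

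The remaining lists held no gene past the threshold over all genes tested, and none passed camera. Median log2 fold changes were 0.12 for unfolded protein response chaperones (camera adjusted p = 0.0588), 0.11 for PPAR targets and fatty acid oxidation (0.0678), and 0.11 for nuclear oxidative phosphorylation genes (0.0906). These lists passed when 1 library was left out, the first without VK1 A (0.0477) and the others without VK1 B (0.0268 and 0.00693). Medians were 0.11 for p53 target genes and for ferroptosis regulators (both 0.217), 0.02 for interferon-stimulated genes (0.217) and 0.05 for NF-kB and TNF response genes (0.191). Further medians were 0.08 for apoptosis regulators (0.3005), 0.07 for autophagy and lysosome (0.309), 0.05 for G2/M and mitosis (0.309), 0.03 for cytosolic ribosomal proteins (0.222) and -0.05 for MYC and ribosome biogenesis (0.222). Those for the heat shock response (0.04, 0.471), ATF4 and the integrated stress response (0.03, 0.644), T-ALL transcription factors and Notch (-0.02, 0.618), metallothioneins (-0.13, 0.618) and mitochondrially encoded genes (0.01, 0.891) lay further from the threshold. Median and mean differed in sign for G1/S and DNA replication (0.01 and -0.001), immediate-early genes (-0.01 and 0.24), AHR and PXR targets (0.20 and -0.008) and glycolysis and hypoxia response (-0.02 and 0.01), with camera adjusted p of 0.644, 0.260, 0.644 and 0.764, and camera called each of these directions up.

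Adjusted over the list alone, 1 ATF4 target and 1 ferroptosis gene (SLC7A11 in both), 1 PPAR gene (CREB3L3), 1 interferon gene (IFI44), 2 immediate-early genes (DUSP6, IER2) and 2 glycolysis genes (SLC2A3, ALDOC) were higher; IER2 and ALDOC were singled out after their values were seen. CREB3L3 had a log2 fold change of 0.71, IFI44, an interferon-induced gene, of 0.59, SLC2A3, the glucose transporter GLUT3, of 0.83, and DUSP6, a phosphatase of ERK, of 0.38, with edgeR adjusted p over all genes of 0.201, 0.0638, 0.290 and 0.362. By DESeq2, CREB3L3 (adjusted p = 0.0293) and IFI44 (0.000116) passed, as did IFI44 without a filter on low counts (edgeR adjusted p = 0.00611). The member with the smallest p in each of the other lists had an edgeR adjusted p of at least 0.368. These were DNAJC3 (log2 fold change 0.18), BAG3 (0.32), FDXR (-0.36), BIK (-0.34), RFC2 (0.29), CDK1 (0.20), BOP1 (-0.30), NDUFA4 (0.36), MT-ND6 (0.53), CD69 (0.60), TCF3 (-0.26), LAMP2 (0.29), SLC30A1 (0.35), TIPARP (0.31) and RPS18 (0.28). Leaving out 1 library moved some of these by over 1.5 times without a change of sign or call, namely FDXR (-0.23), TIPARP (0.13) and CDK1 (0.30) without Control 1, TIPARP (0.51), CDK1 (0.10) and BOP1 (-0.17) without Control 2, CDK1 (0.13) without VK1 B, and TCF3 (-0.17) without VK1 C.

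Markers of other cell types were rarely tested and none passed. The 4 tested myeloid markers had a median log2 fold change of 0.46, the 3 B cell markers -0.28, the 2 natural killer and cytotoxic markers 0.20, the 2 epithelial and fibroblast markers -0.08 and the 1 erythroid and megakaryocyte marker -0.12. Of the lists that track RNA quality, replication-dependent histones had a median of -0.05 (camera adjusted p = 0.618) and short and non-polyadenylated RNAs 0.36 (0.0653, and 0.0296 without Control 1).

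By DESeq2 74 genes were higher and 38 lower, and without a filter on low counts 54 and 32. Leaving out Control 1 or Control 2 gave 39 or 43 higher and 20 lower in each case, and leaving out VK1 A or VK1 B gave 18 or 16 lower.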

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

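The alternative without the 117 genes at 2 levels in a pattern other than Control against VK1 was chosen after seeing the data, and all others before. All 32 calls were shared with RLE scaling, upper-quartile scaling, both other filters, DESeq2 and the fit without those 117 genes, and the 22 calls of limma-voom were all among them. Without a filter on low counts 54 genes were higher and 32 lower, with DESeq2 74 and 38, and with a minimum log2 fold change of 1, which can only remove calls, 13 and 5. Leaving out 1 library at a time gave 20 to 43 higher and 11 to 20 lower, with 21 to 26 of the 32 calls shared; the cause was not tested. Of 16 genes past the threshold that the naming rule covers, STAMBP and FADS1 lost their call without Control 1, Control 2, VK1 A or VK1 B and with limma-voom, and 14 kept it in each alternative fit. RAG1, SREBF1, STAMBP and FADS1 lie under the minimum log2 fold change of 1. VKORC1L1 changed sign without Control 2, VK1 B or VK1 C, with log2 fold changes of -0.0238 to 0.0619 over the libraries left out. With an estimated correlation 1 list passed, that of cholesterol genes, in place of 5. The estimate was below the preset 0.01 for cholesterol genes (-0.011), NRF2 targets (-0.013) and LXR targets (-0.093). This argues against a larger correlation as the reason for the change in these lists. The estimate was above 0.01 for fatty acid synthesis (0.043) and the T cell list (0.087). With an estimated correlation camera refers to the 3 residual degrees of freedom of the fit, and with a preset one it does not. This alone raises the p-values, so a list that failed there is not shown to depend on correlation between genes. The share of each cause was not tested. The T cell list lost its call without Control 2 (adjusted p = 0.160) and without VK1 C (0.0912), and the fatty acid list without Control 1 (0.0603). By fry, which tests whether a list moves one way and not against other genes, the T cell list did not pass (0.0968). Divisions that set 1 Control and 1 VK1 library apart from the others gave 0 to 2 lists past camera. The cholesterol list was not among these (camera adjusted p of 0.295 or more). Divisions that join both Control libraries with a VK1 library keep much of the real difference and gave 1 to 5. At 11110128 to 14537759 counts per library, simulated changes of 1.5-fold were recovered in 26.2% of genes. No paired analysis was possible because the VK1 columns carry no replicate number of the labels.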

Other observations

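The tests of the last exon, of the direction of the cholesterol genes and LXR targets and of the share of genes at 2 levels among genes past the threshold were chosen only after the result was seen. Among 272 KEGG terms, tested as exploration, 4 stood above the other genes by camera and none below. With an estimated correlation none of the 4 passed (adjusted p = 0.990 for each). That test rests on 3 residual degrees of freedom and is adjusted over 272 terms. It could hardly pass any term, so it decides nothing about these 4. The Proteasome term, which holds the subunits of the main protein-degrading complex, had 38 of 42 tested genes with a positive log2 fold change, a median of 0.21 and an adjusted p of 2.281e-08. None of its genes passed edgeR's test, in which 1121 of all genes had an unadjusted p under 0.05. PSMD14 had a log2 fold change of 0.39 (adjusted p = 0.170), PSMC6 0.38 and PSMC2 0.38. The other terms were Steroid biosynthesis (adjusted p = 1.349e-11), Terpenoid backbone biosynthesis (0.00577) and Fatty acid metabolism (0.0104). Of their tested genes, 12 of 17, 8 of 19 and 1 of 46 were in the cholesterol list. The last term also holds SCD and FADS1, so these terms are not independent of the lists above.

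In some genes the libraries fell at 2 levels at least 2-fold apart. Of 8045 genes with a mean of at least 20 CPM, 126 (1.57%) did so, 117 in a pattern other than Control against VK1 and 9 in it. The 9 included UBFD1, GLO1, MAP1S and JMJD4 and, among cholesterol genes, INSIG1, MSMO1, IDI1 and SQLE. PRNP was at 30.0 CPM in Control 2 and at 198 to 227 CPM in the other libraries. OIP5-AS1 was at 40.5 CPM in Control 1 and at 253 to 270 CPM in the others. TRIM56 was at 87.8 and 89.0 CPM in Control 1 and VK1 A and at 7.74 to 12.3 CPM in the others. These genes were singled out after their values were seen.

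For the 117 genes, depth alone is argued against, since VK1 C, the shallowest library, was the low one in a share of 0.185 of the 54 genes with 1 library low. Reads passing to an overlapping gene are also argued against as the main source, since a share of 0.103 (12 of 117) overlapped a gene moving the opposite way. The median longest last exon was 1.6 times that of genes matched on CPM (3059 against 1912 bp, permutation p recorded as 1e-05, 100000 permutations). Very small p-values were all recorded as this value, so the exact one may be somewhat larger. A candidate explanation is that long 3' ends were counted in some libraries and not in others. No biological explanation was tested.

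The 15 genes past the threshold outside the lipid lists were weighed as genes at 2 levels that happened to follow the groups. The 9 other divisions of the 5 libraries into 2 and 3 gave a median of 9 genes (6 to 17), and of those with a mean of at least 20 CPM a share of 0.569 (37 of 65) were at 2 levels in the pattern of their division. Of 14 such genes in the real division a share of 0.286 were, so counts at 2 levels may account for these 4 (UBFD1, GLO1, MAP1S and JMJD4). ZNF551, with a mean of 13.2 CPM, was not assessed, so for it such counts and an effect of VK1 cannot be told apart. The other 10, RAG1 among them, did not meet the rule, which needs a gap of at least 1 on the log2 scale. RAG1 changed by -0.86, so the rule could not call it, and smaller jumps of this kind are not excluded for the 10. Of the other divisions, 8 gave 0 to 3 genes without such counts and the one that sets VK1 B and VK1 C apart gave 11; it joins both Control libraries with VK1 A and so is no clean null, but the 2 others that join both with a VK1 library gave 0 and 3, and with 10 divisions no share under 0.05 can be had, and an effect of VK1 on the 10 stays open. The median longest last exon was 2350 bp in the 15 genes and 1693 bp in genes past the threshold in the lipid lists, a difference that was not tested.

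The rise of the cholesterol genes and the fall of LXR targets were weighed against the same explanation. The planned test, the largest list median in the other divisions, gave 0.594 for cholesterol genes and 0.361 for LXR targets, against 0.854 and 0.381 in the real one. It decides nothing, since divisions that join both Control libraries with a VK1 library keep much of the real difference by design. Of the 21 cholesterol genes with a mean of at least 20 CPM, 5 were at 2 levels that followed the groups. All 24 tested had a positive log2 fold change. Independent genes at 2 levels go either way (in 26 of 41 the 2 libraries apart were the low ones). They would give 11 to 20 positive members (95% binomial range, up to 22 at the upper end of that share's interval). This argues against the explanation for that list as far as members vary independently. The range treats all 24 as genes at 2 levels, whereas 6 were. In the LXR list 6 of 7 had a negative log2 fold change, against a range of 0 to 5 (up to 6 at the upper end). This count decides nothing, since only 3 of the 7 reached 20 CPM. SREBF1 changed by -0.84 on the log2 scale, so the rule, with its minimum gap of 1, could not call it. ABCG1 and MYLIP lay below 20 CPM and were not assessed. For all of these, jumps in counts between libraries and an effect of VK1 cannot be told apart. A solvent effect stays open for both lists.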
